A study of Oryza sativa with 4 samples.

How the data were processed

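Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measured where the rice MADS-domain protein OsMADS2 lay on the genome in young panicles of the wild-type line TP309. Per the labels' protocols, panicles of 0.3 to 2 cm (about 200 mg) were fixed with 1% formaldehyde, and chromatin was cut by micrococcal nuclease to fragments of 150 to 900 bp. For each immunoprecipitation 8 µg of chromatin met 6 µg of purified anti-OsMADS2 antibody, and a mock immunoprecipitation with rabbit IgG was handled alike. The labels give 2 groups of 2 libraries, OsMADS2 and IgG mock, numbered 5 and 6 in the titles, and per the file headers the numbers stand for 2 biological replicates. They are called IP5, IP6, mock 5 and mock 6 below.

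The submitters' processing notes name fastp, Bowtie2, SAMtools, deepTools and MACS2, without versions or settings. The genome build is not given in the sources used here, so coordinates are printed as the authors deposited them. The authors deposited read counts per library (raw, mapped and uniquely mapped). They deposited 3 peak lists, each of 1 IP library over 1 mock library and not pooled: IP5 over mock 5, IP5 over mock 6 and IP6 over mock 6. Each peak has a fold enrichment by the authors' peak caller, with mock as the control, and −log10 values of p and q, also deposited by the authors. At CYCLIN-P4-1-LIKE the fold of IP5 was 9.11 over mock 5 and 9.11 over mock 6. A fold is therefore not always a plain ratio of IP to mock signal. These folds and q-values are the authors' own and describe peaks within 1 list. Summits were not used here. Per the file headers, peaks overlapping in all 3 lists were merged by the authors and assigned to nearby genes, which gave the regions called confident below. The largest distance from such a region to a gene is 3999 bp. Motifs came from MEME-ChIP 5.4.1 with the JASPAR 2022 plant collection, per the last lines of that table. The tool and background behind the authors' gene ontology (GO) values are not given in the sources used here.

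Overlap between lists was counted at 1 bp or more. Chance overlap came from 1000 random placements, in which each peak kept its width and moved to a uniform position on its chromosome, with a one-sided permutation p and Benjamini-Hochberg adjustment over the 3 pairs of lists. The smallest p that 1000 placements can give is 0.001. Chromosome lengths were taken as the largest peak end over the 3 lists. Median fold of shared and unshared peaks was compared within each list by a two-sided permutation test with 100000 resamples, smallest p 1e-05. Regions called in all lists were rebuilt by merging peaks that overlap by 1 bp or more. Gene positions came from the authors' gene table. Gene starts and gene ends touched by confident regions were compared by an exact two-sided binomial test with Clopper-Pearson 95% intervals. Other shares have Wilson 95% intervals, which cover counting error only. Simulated lists with known sharing were used to test the overlap counts. For IP6 over mock 6 against IP5 over mock 5, with 10602 simulated peaks, planted sharing of 0%, 10% and 30% came back as -0.338%, 9.79% and 29.7%. Counts matched those of bedtools 2.31.1. Simulated peaks were placed uniformly, as in the chance placements, and planted peaks always overlapped. The simulation therefore checks the counting alone and not the effect of clustered peaks. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

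Before the data were examined, 4 gene lists with 68 members (floral MADS genes, flowering time, panicle and meristem, auxin) were written from textbook knowledge, and each was tested by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 4 lists. The background, 29427 protein-coding genes, is a gene number from a RefSeq annotation of another assembly (ASM3414082v1) and approximates the genes that could have been assigned. Of the 2589 genes in the gene table, 0 had their identifier in that annotation, nor had any list member (0 of 68), so the planned check of list identifiers against a reference was not made. The 7 members found near a region were checked against the symbols in the gene table instead. A member whose identifier was recalled wrongly would count as having no region.

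The rule for named genes took all list members near a confident region, plus the 10 genes of highest fold. The confident table has no fold, so the 5 highest from IP5 over mock 5 were taken first and then the 5 highest from IP6 over mock 6 among genes not already taken, with the nearest gene per region and the highest peak within each region. For motifs and GO terms the rule took the 5 with the smallest values. The members named for each GO term (the 3 of highest IP6 fold) and the terms inflorescence development and flower development were chosen after the data were seen. The start-against-end test was also chosen then. It stands in for a planned placement test of gene positions, which needs an annotation in the coordinates of the files.

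Alternatives tried were a reciprocal overlap of 50% (200 placements), q below 0.01, fold of at least 5, mock 6 as the control for IP5, and a circular shift of the list. For positions a 1 kb window was tried, and for gene lists a narrower gene assignment. Those added after the data were seen were shifts of 10 to 50 kb, a fold of at least 2, the lists without either replicate, a background of 39387 genes, and other ways of counting starts and ends. A search for the CArG box, the textbook site of MADS-domain proteins, was planned. It was not run because no genome sequence was used here.

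Unique reads numbered 9142837 for IP5, 15934402 for IP6, 13248694 for mock 5 and 16742118 for mock 6. The widest Wilson interval of any mapped or unique share of reads was 0.0411 percentage points.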

Results

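OsMADS2 binding was profiled by ChIP-seq in rice panicles of 0.3 to 2 cm. OsMADS2 is a PISTILLATA-like MADS-domain protein, a class of floral regulator known for its part in petal (in grasses, lodicule) and stamen identity. The data were 2 OsMADS2 immunoprecipitation libraries (IP5 and IP6) and 2 IgG mock libraries (mock 5 and mock 6). IP5 held 22099123 raw reads, of which 9142837 (41.4%) mapped uniquely. IP6 held 29860585 raw reads, with 15934402 unique (53.4%). The mock libraries had more raw reads, 32396307 for mock 5 (40.9% unique) and 39011241 for mock 6 (42.9% unique). In unique reads mock 5 (13248694) was below IP6.

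The first question was where OsMADS2 immunoprecipitation exceeded mock in each library. Within the authors' confident gene table, the regions of highest fold in IP5 over mock 5 lay at the start of CYCLIN-P4-1-LIKE (Os07g0231500, chromosome 7, 7313351 to 7314608) and of Os03g0765900 (chromosome 3, 31723337 to 31725797). The CYCLIN-P4-1-LIKE region reached a fold of 9.11 in IP5 over mock 5 and 11.7 in IP6 over mock 6. That 11.7 peak (7313272 to 7313667) starts before the region and is absent from the authors' sheet of shared peaks. The Os03g0765900 region reached 9.01 and 9.49. Higher folds occurred outside that table, for example an IP5 over mock 6 peak of 12.7 (chromosome 5, 16152133 to 16152681) that overlaps the 3′ end of OsWRKY53, and an IP6 peak of 23.8 (chromosome 5, 12887979 to 12888661). The highest fold of any list, 31.7, was an IP6 over mock 6 peak (chromosome 6, 28182610 to 28182841) that is in the authors' sheet of shared peaks. Folds are the authors' values for single library pairs, so they carry no replicate error. IP5 gave 24169 peaks over mock 5 and 58213 over mock 6, while IP6 gave 10602 over mock 6. The deeper IP library thus had the shorter list. The peaks covered 7.59 Mb, 20 Mb and 2.77 Mb, with median widths of 265, 292 and 209 bp. Median folds were 3.03, 2.77 and 2.73, and the largest q in any list was 0.0499. At a fold of at least 5 the counts were 898, 453 and 161.

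Whether the same places were bound in both replicates was asked of IP5 over mock 5 and IP6 over mock 6, which share no library. The genes named here come from the authors' confident table, which requires a peak in all 3 lists. Their recurrence was therefore given by that choice, and only the size of their folds is informative. Regions at 3 of them had high folds in both calls: CYCLIN-P4-1-LIKE, Os03g0765900 and OsPHD20, a PHD-finger gene whose region lay 2309 bp downstream (8.12 and 8.35). Others were strong in 1 call and in the other near 2.00, the smallest fold in the authors' sheet of shared peaks. OsG1L8, an ALOG family gene, had 2.04 in IP5 over mock 5 and 9.46 in IP6 over mock 6 at its start. Os04g0378400 had the opposite order, 7.76 and 2.21, in a region 542 bp downstream. Of the 10602 IP6 peaks, 1859 (17.5%) overlapped an IP5 over mock 5 peak, against 399.1 ± 19.7 (SD over placements) by chance. That is 4.66 times chance (one-sided permutation p = 0.001, the smallest possible, adjusted p = 0.001). Uniform placement ignores where reads can map, and with shifts of 10 to 50 kb the ratio was 3.77. The excess shows that the 2 calls recur at the same places, but it cannot tell OsMADS2 binding from signal common to both replicates for other reasons. In the other direction 1803 of 24169 IP5 peaks (7.46%) overlapped. With reciprocal overlap of 50% the number fell to 930, which was 8.32 times chance. At a fold of at least 5 in both lists it fell to 24 of 161 IP6 peaks (14.9%), against 0.317 by chance, a ratio of 75.7.

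The other pairs of lists share a library, and part of their excess over chance may therefore come from it. IP6 and IP5 peaks called over the same mock 6 shared 4052 of the 10602 IP6 peaks (38.2%), 3.99 times chance. IP5 over mock 5 and IP5 over mock 6 shared 17088 of 24169 (70.7%), 6.97 times chance. Both had permutation p = 0.001.

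Shared peaks had a slightly higher median fold than unshared ones in each list. In IP5 over mock 5 the medians were 3.18 and 3.02, a difference of 0.159, while the lower quartiles were 2.46 for shared and 2.49 for unshared peaks. In IP6 over mock 6 they were 2.97 and 2.73, a difference of 0.243. Each permutation p was 1e-05, the smallest possible. Peaks are not replicates, so these p-values describe the 2 lists only. With mock 6 as the control for IP5 the difference was 0.712 for IP5 peaks and 0.131 for IP6 peaks. By decile of fold, the share of IP6 peaks found in IP5 was 17.6% in the lowest decile, 10.2% in the fourth and 40.8% in the highest. For IP5 over mock 5 peaks found in IP6 it was 8.67% in the lowest, 5.04% in the fifth and 16.0% in the highest. IP6 peaks of the highest decile were also wider (median 308 bp, against 201 bp in the fourth). Chance overlap there was 4.83%, against 3.62% in the fourth.

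**Figure D1:**
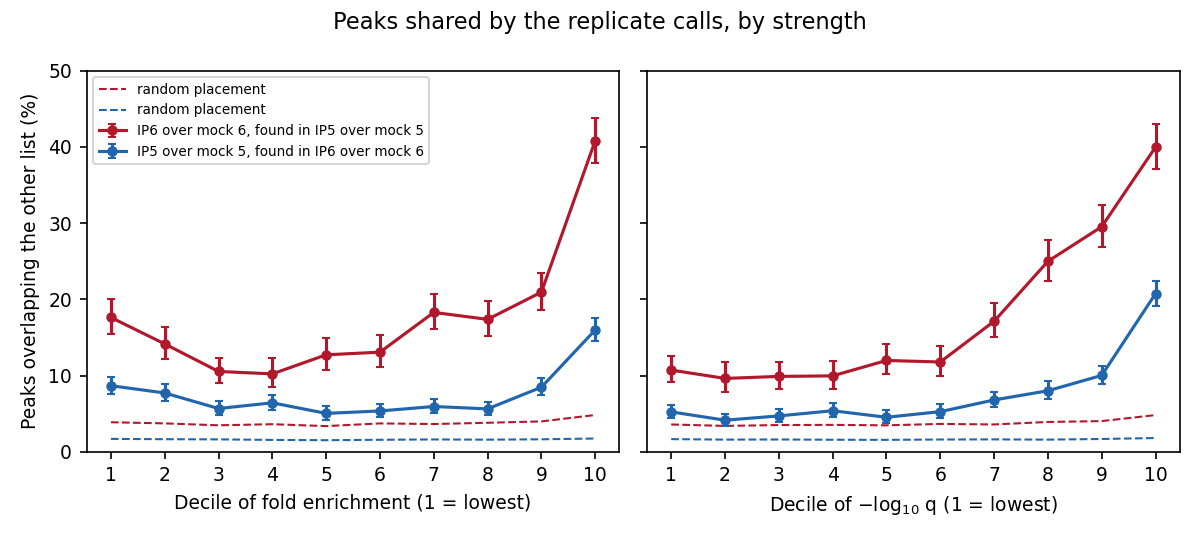
Percentage of peaks overlapping the other replicate call (y axis) by decile of fold enrichment (left) or of −log10 q (right); points are deciles, bars are Wilson 95% intervals and dashed lines are the mean of 50 random placements. IP6 over mock 6 peaks (red) reach 40.8% in the top fold decile and IP5 over mock 5 peaks (blue) 16.0%.

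The next question was which regions recurred across all 3 lists and which genes lay near them. The authors' confident table holds 1442 regions with 2589 genes in 2862 region-gene pairs, with a median of 2 genes per region. All 1442 overlapped a peak in each list, which the authors' rule for the set requires. Merging the deposited lists gave 1811 regions with peaks in all 3, and 1542 after peaks with a fold below 2 were left out. The smallest folds in the authors' sheet of shared peaks were 2.00, 2.00 and 2.00 for the 3 lists. Region numbers run to 1534, so 92 numbers have no gene row. Because 2 of the 3 lists share IP5 and 2 share mock 6, membership of this set rests on fewer independent comparisons than 3. Only the overlap of IP5 over mock 5 with IP6 over mock 6 is free of shared libraries. Merging chains peaks, and only 1803 IP5 over mock 5 peaks overlapped an IP6 peak, fewer than the 1811 regions. Some of those 1811 regions therefore join the 2 calls only through an IP5 over mock 6 peak.

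Confident regions lay at the starts of genes far more than at their ends. Examples from the fixed lists are OsMADS14, OsMADS56, OsGI, SNB, OsSPL14 and OsAFB2, each with a region across the start. A region overlapped a gene start in 618 pairs and a gene end in 138, a share of 81.7% (exact 95% interval 78.8 to 84.4, exact binomial p = 2.72e-73, two-sided). Pairs that share a region are not independent; counted by region, those touching only 1 kind of end gave 538 starts and 71 ends. Midpoints clustered just inside the gene, with 470 pairs within 250 bp downstream of the start and 133 within 250 bp upstream. Of the 1442 regions, 870 (60.3%, Wilson 95% interval 57.8 to 62.8) overlapped a start or had a midpoint up to 2 kb upstream of one. Another 420 (29.1%) had a midpoint in a gene body, and 152 (10.5%) lay farther away. With a 1 kb window the first share was 52.0%. The table lists only regions within 4 kb of a gene, and no genome-wide expectation was computed.

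**Figure D2:**
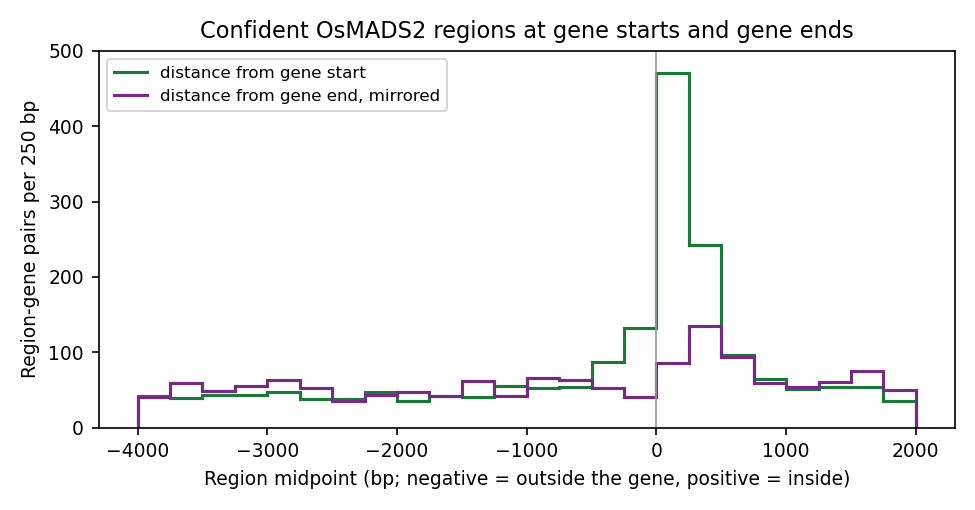
Number of region-gene pairs per 250 bp (y axis) by distance in bp from the region midpoint to the gene start (green) or the mirrored gene end (purple); negative values lie outside the gene. The highest bin holds 470 pairs and lies from 0 to 250 bp inside the gene start.

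Among the lists fixed beforehand, 2 of 20 floral MADS genes had a confident region. OsMADS14 and OsMADS18 are both relatives of APETALA1 and FRUITFULL, which act in meristem and floral identity. The OsMADS14 region (chromosome 3, 31041417 to 31042057) crossed the gene start, with folds of 2.25 in IP5 over mock 5 and 2.47 in IP6 over mock 6. The OsMADS18 region (chromosome 7, 24787931 to 24788428) lay 47 bp upstream, with folds of 3.22 and 4.00. The gene table gives OsMADS2 as a synonym of this OsMADS18 entry, Os07g0605200. The identifier of OsMADS2 itself in the fixed list, Os01g0883100, was not in the confident gene set.

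Flowering time genes had 2 of 21 members with a region, both across the gene start. OsMADS56, a SOC1-like regulator, had folds of 2.11 and 2.90 (chromosome 10, 20862956 to 20864122). OsGI, the rice GIGANTEA clock gene, had 3.11 and 4.03 (chromosome 1, 4338223 to 4338813). Panicle and meristem genes had 2 of 20, again across the gene start. SNB, an AP2 gene of the spikelet meristem, had 3.04 and 4.05 (chromosome 7, 7545373 to 7545752). OsSPL14, known for its part in tillering and panicle branching, had 2.55 and 2.04 (chromosome 8, 25278447 to 25278718). Its peak in IP6 over mock 6 had a q of 0.0117, above the stricter setting of 0.01. Of 7 auxin genes only OsAFB2, an auxin receptor gene, had a region, with 3.20 and 3.04 across its start (chromosome 4, 19457476 to 19458661). The table also gives OsTIR1 as a synonym of that entry.

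Each list held more members with a region than expected, by less than 1 gene, and none passed the test. The expected numbers were 1.76 floral MADS, 1.85 flowering time, 1.76 panicle and meristem and 0.616 auxin genes. Odds ratios were 1.15, 1.09, 1.15 and 1.73 (one-sided Fisher's exact test, adjusted p = 0.563 for each). With only regions in the gene or up to 2 kb upstream counted, the odds ratios were 2.08, 1.97, 2.08 and 3.12, and again none passed (one-sided Fisher's exact test, adjusted p = 0.306 for each). The exact 95% intervals of the shares were wide, for example 1.24% to 31.7% for floral MADS genes.

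**Figure D3:**
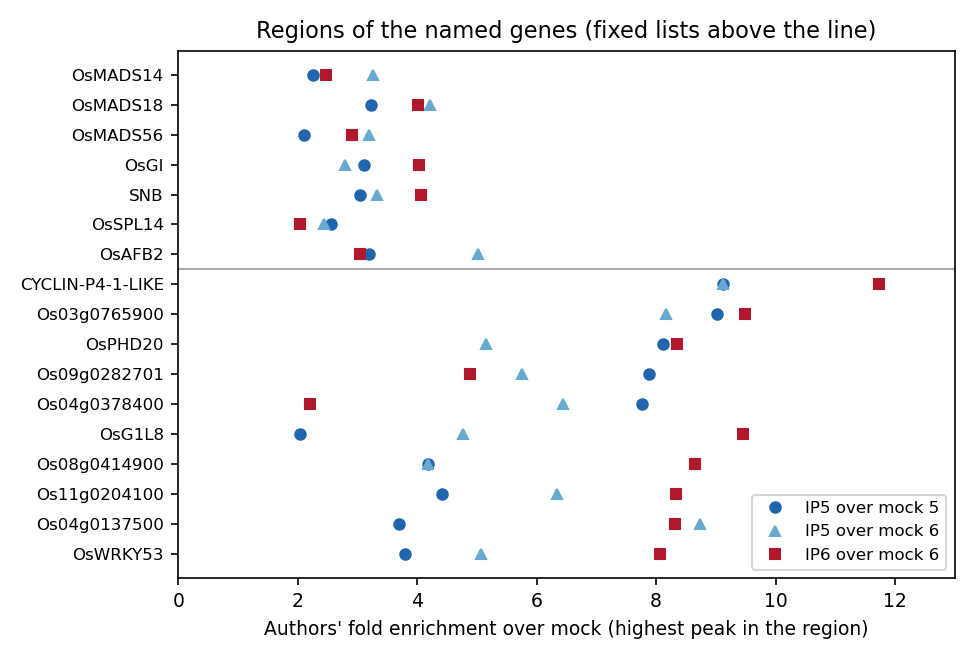
Fold enrichment by the authors' peak caller (x axis) for the highest peak in the region of each named gene, in IP5 over mock 5 (circles), IP5 over mock 6 (triangles) and IP6 over mock 6 (squares). Genes of the fixed lists lie above the line, from 2.04 to 5.02, and genes of highest fold below it, up to 11.7.

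The remaining genes of highest fold included OsWRKY53, a WRKY transcription factor gene, with a region across its start (chromosome 5, 16149883 to 16151850) and folds of 3.80 in IP5 over mock 5 and 8.07 in IP6 over mock 6. Os08g0414900 had 4.19 and 8.66 in a region 65 bp upstream. Os11g0204100 had 4.42 and 8.34, and Os04g0137500 3.69 and 8.32, both across the gene start. Os09g0282701 had 7.88 and 4.88 in a region 659 bp downstream.

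GC-rich repeats stood first by E-value among the motifs found in the regions, beside AT-rich and other kinds. Base composition of the regions was not compared with that of other sequence. In the authors' deposited table of 105 motifs the first, GCGGCGGCGGCGRC, had an E-value of 8.7e-221 at 532 sites, and the second was a T-rich run, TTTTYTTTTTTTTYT, with 4.1e-94 at 119 sites. The next 3 in the authors' deposited table are centrally placed JASPAR motifs, named by the maize genes Zm00001d005892 (4.2e-54), Zm00001d020267 (9.5e-51) and Zm00001d024324 (4.1e-48). Each has a consensus of CCG repeats. The E-values of the first and second motif came from MEME, and those of the next 3 from CentriMo, a test of central position. The order therefore mixes unlike measures. A GCC repeat stood in the consensus of 44 motifs, and 68 were named for AP2/ERF genes. Many of these consensus sequences are alike, so the counts are not of independent signals. The share of AP2/ERF motifs in the collection searched was not computed, so no enrichment of that family can be read from them. By the same search of names and consensus sequences, 0 were named for a MADS gene and 0 contained a CArG box. Motifs named only by a maize identifier could not be assigned to a family.

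In the authors' deposited table of 77 GO terms, the smallest false discovery rates were for transcription (34 of 208 genes, 5.53e-04), beta-mannosidase activity (3 of 3, 0.00104), transcription cofactor activity (9 of 32, 0.00212), response to nitrate (17 of 87, 0.00222) and auxin mediated signaling pathway (27 of 167, 0.00246). The auxin genes included OsIAA3, with a region 3543 bp downstream and folds of 5.66 in IP5 over mock 5 and 6.20 in IP6 over mock 6. They also included the auxin response factor genes OsARF1 (4.31 and 4.85, across the start) and OsARF2 (2.04 and 4.89, 57 bp upstream). The nitrate genes included OsNRT1.1A, a nitrate transporter gene with a region across its end (6.40 and 4.67). Others were OsPTR2, with a region 1482 bp downstream (2.42 and 6.54), and the proton pump gene OSA7 (2.98 and 5.05, across the start). The PHD-finger genes OsPHD20, OsPHD35 (4.75 and 4.61) and OsPHD40 (3.33 and 5.13) led the cofactor term. All 3 beta-mannosidase genes are beta-glucosidase family members. Os3bglu7 and Os3bglu8 share 1 region (4.68 and 3.87), which lies inside Os3bglu7 and 3566 bp downstream of Os3bglu8. Os7bglu26 had 6.29 and 2.11. That term therefore rests on fewer regions than the 3 genes counted, and genes that share a region are not independent.

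In the authors' deposited table inflorescence development (49 of 372 genes) had a false discovery rate of 0.00512, and its members included OsMADS14, OsMADS56, OsGI and OsSPL14. Flower development (15 of 88) had 0.015 in the authors' deposited table, with SNB, OsGI, OsMADS14 and OsMADS18 among its members. All 77 deposited rates were 1.40 to 1.51 times a hypergeometric p computed with a fitted background of 29150 genes. That hypergeometric p, before any adjustment, was 0.00354 for inflorescence development and 0.0104 for flower development. At 0.05, a Benjamini-Hochberg adjustment of it would pass any of the 77 terms only if no more than 156 were tested. The number tested was not known here. The deposited rates therefore cannot be read as adjusted for all terms tested.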

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

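All tests of explanations in this part were chosen after the results they bear on were seen.

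Of 5 regions called in all 3 lists that hold a peak with a fold from 10 to below 20, 4 are absent from the authors' sheet of shared peaks. They lie on chromosome 1 (6201513 to 6201878, fold 10.8 in IP5 over mock 5), chromosome 5 (16152133 to 16153031, 12.7 in IP5 over mock 6), chromosome 6 (23935597 to 23936641, 10.7 in IP6 over mock 6) and chromosome 10 (17191071 to 17191946, 10.2 in IP5 over mock 5). They passed the same peak calls as the regions kept and stand among the highest folds of their lists, which is why they were singled out. Another 2 regions called in all 3 lists at a fold of 2 or more are absent from the sheet without any such peak, both on chromosome 8 (3548822 to 3550552, folds of 2.76 to 5.11, and 8258033 to 8258960, folds of 2.06 to 4.54).

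An upper limit on fold is argued against by a kept peak with a fold of 31.7, a single peak. A candidate explanation is a minimum fold of 2 compared as text, under which 10.8 sorts below 2. In regions called in all 3 lists, 4697 of 4924 peaks with a fold of 2 to below 10 are in the sheet, against 0 of 5 from 10 to below 20, but this rule would keep both chromosome 8 regions, gives 1538 regions where the authors number 1534, and recovers the exact coordinates of 1417 of the 1442 listed regions, against 1416 under the numeric rule. The region numbers equal the rank of 1268 regions under the text rule and of 49 under the numeric rule, but 1 extra region early in the order shifts every later rank, which widens that contrast, and the rules were compared only after 6 minimum folds and 3 merge gaps had been tried. Removal of strong regions by position stays open: only 1 of the 5 regions, at CYCLIN-P4-1-LIKE, was kept through its other peaks without its strongest one, and no biological explanation was tested.

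On ChrSy, a sequence apart from the 12 chromosomes and without a row in the gene table, 2 regions had peaks of fold 2 or more in all 3 lists. The numbering of the confident regions has 92 numbers without a row in the gene table, so the positions described cover the 1442 listed regions alone.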

How the results depend on the processing

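Of 35 alternative settings, 25 kept the direction and the side of the threshold, or stayed close to the reported count, and 10 moved a count or share. Settings added after the data were seen were the 10 to 50 kb shifts (3.77 times chance), the minimum fold of 2 (1542 regions), the versions without a replicate, the all-gene background and all counts of starts and ends. A minimum fold of 5 left 898, 453 and 161 peaks in IP5 over mock 5, IP5 over mock 6 and IP6 over mock 6, and 24 shared IP6 peaks, as fewer peaks enter. Reciprocal overlap of 50% left 930 shared IP6 peaks and 689 regions in all lists, and mock 6 as the control for IP5 gave 4052 shared IP6 peaks, with a longer IP5 list and a shared mock at once, which were not separated. The 1 kb window gave 52.0% of regions at starts. Without replicate 6 or 5 the recurring set is simply 1 list, from 10602 to 24169 peaks. The ratio of sharing to chance stayed between 3.77 and 75.7 over the 6 alternatives run on it, and adjusted p for the gene lists between 0.306 and 0.406 in theirs.

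No paired analysis was possible because peak lists give no value per library and so nothing to fit a block on; the lists of IP5 over mock 5 and IP6 over mock 6 are themselves the same-numbered pairs. Not run were the CArG search with its alternatives, the placement test of positions, the 5 kb windows, the length-matched background, summit overlap, and the versions of positions and gene lists without a replicate, which need a genome, an annotation or summits not used here. With 2 libraries per group, depth and replicate cannot be separated: IP6 had 1.74 times the unique reads of IP5 and mock 6 had 1.26 times those of mock 5.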

Other observations

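Tests of explanations in this part were chosen after the results were seen, as were the genes named next. A search of the gene table for symbols of the fixed lists met 2 further genes that carry such a symbol under another identifier. The lists give OSH1 as Os03g0727000 and LAX1 as Os01g0831000. YAB2 (Os03g0650000), a YABBY gene also called OsSH1 and known from seed shattering, had a region inside the gene (chromosome 3, 25197367 to 25197783) with folds of 3.77 in IP5 over mock 5 and 2.72 in IP6 over mock 6. OsLAX1 (Os01g0856500), also listed as OsAUX1, had a region inside the gene (chromosome 1, 36998353 to 36999613) with 2.36 and 2.81. Among genes of the inflorescence development term, bc12 had 2.05 and 4.90 in a region inside the gene, and Os04g0636900 had 4.87 and 5.71 in a region 3168 bp downstream. More than 1 confident region was assigned to 254 genes, with up to 4 regions for 1 gene, and 58 regions covered a whole gene. Starts of genes on both strands were overlapped by the same region in 12 cases. The raised share of IP6 peaks found in IP5 over mock 5 in the lowest decile held for fold (17.6%, against 10.2% in the fourth) and not for q (10.7%, against 9.96%).

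IP5 peaks that depended on the mock library differed in how often they recurred in IP6. Peaks called over both mocks overlapped IP6 over mock 6 in 1731 of 17088 cases, 5.97 times chance. Peaks called over mock 6 alone did so in 2080 of 41043, 2.99 times chance (permutation p = 0.001), but those called over mock 5 alone in 72 of 7081, 0.695 times chance (one-sided permutation p for fewer = 0.002). The last class was selected for failing over mock 6 and was compared with a list called over mock 6, so a low overlap is built into it, and neither the mock libraries nor OsMADS2 binding can be judged from these ratios.

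The false discovery rates deposited for GO terms followed a fixed multiple of a hypergeometric p. With 2589 genes and a background fitted at 29150, the ratio of deposited rate to p had a median of 1.44, a highest over lowest of 1.08 and an SD of log10 of 0.00621. The background was fitted on these terms, and the criterion was changed to the smallest SD after a constant offset was noticed, so part of the tightness comes from fitting. When rates were simulated as Benjamini-Hochberg values over the listed terms and fitted in the same way, the SD was 0.191 or more and the highest over lowest 11.1 or more, so that adjustment is argued against. A rate set as 1 constant times p is a candidate explanation; at 0.05, a Benjamini-Hochberg adjustment of the fitted p would pass any term only if no more than 156 were tested.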
